A study of Homo sapiens with 6 samples.

How the data were processed

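The series holds bulk RNA sequencing of HaCaT cells, an immortalised human keratinocyte line, as parental wild-type cells and as cells in which MAPK14, the gene of p38α, was knocked out according to the labels. Cells received PBS (unstimulated) or IL-1α for 4 h. The 6 libraries form 4 groups: 1 unstimulated and 2 IL-1α libraries of each genotype. RNA was extracted with TRIzol and RNeasy columns and libraries were made with a stranded poly-A TruSeq mRNA kit. The labels do not say whether the replicates came from separate cultures or from separate clones, so each p-value measures the spread between these samples only. They also do not describe the edit made in MAPK14.

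Upstream steps were those of the submitters: bcl2fastq (2.20.0.422), alignment with STAR and counting with HOMER, the last 2 without stated versions, on the hg19 build. The deposited table, made with HOMER's analyzeRepeats in exon-counting mode with 1 line per gene symbol, held RPKM for 27945 genes. Per the file headers the unit is also written FPKM, and the strand setting of the counting is not stated, so transcripts that overlap a gene on the other strand may be included in its value. Values were used as deposited. Library depth was recovered as the number of reads that turned the values of RPKM 0.02 to 1 into whole counts, with a tolerance of 0.1 read; between 99.5% and 100% of those values became whole. Rebuilt reads served for counting intervals and for voom only. Coordinates are those of the deposited table.

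Genes annotated at more than 1 place were mostly listed at 0 in every library: 671 of 908, and among protein-coding genes 356 of 486 against 2729 of the 18989 with 1 place. TNF, LTB, HLA-E, TAP1 and RPS18, which lie in such regions, were therefore not measured. In all, 7424 genes were listed at 0 everywhere.

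The design, the gene lists, the rule for naming genes and most of the other settings tried were fixed before the data were examined. Genes with at least 1 RPKM in at least 1 library (12925) were analysed as log2(RPKM + 0.5) in limma (3.58.1, R 4.3.3) with 1 coefficient per group, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. Residual variance came from the 2 replicated groups alone (2 residual degrees of freedom, 4.2 prior degrees of freedom). Tested contrasts were the IL-1α response in each genotype, knockout against wild type under IL-1α, and the genotype by IL-1α interaction. The unstimulated genotypes, with 1 library each, were compared by fold change alone: at least 2-fold with at least 1 RPKM in the higher library. No p-value is given for that comparison, since neither group has a replicate.

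Gene lists (32 lists, 763 entries, of which 761 matched a symbol in the table) were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Camera compares a list with all other genes, so its up and down are relative to them and not to 0. The second form draws on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. The cytokine list in wild type, with an estimated correlation of -0.035, went from camera p = 3.47e-13 to p = 0.0159. Calls lost with this form therefore do not by themselves measure correlation between members. Some lists had higher estimates, 0.366 for antimicrobial genes and 0.32 for CXC chemokines, against 0.078 for interferon-stimulated genes and 0.034 for NF-κB genes. In the lists with high estimates correlation may account for part of the loss. Calls within a list were also adjusted over the list alone. For the unstimulated comparison the median of a list was placed among 10000 random lists matched on expression in 25 bins and given as a percentile. Keratins, SPRR2 genes, CXCL1 to CXCL3, serum amyloid A, SERPINB3 and SERPINB4, galectin-7 genes and histones have close relatives among which reads may be shared, so their separate values are uncertain.

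Named genes were, for each comparison, the 10 with the largest rise and the 10 with the largest fall among those passing with a higher group mean of at least 5 RPKM, leaving out antisense, LOC, LINC and pseudogene symbols. Added to these were up to 4 passing members of each list by size of change, the 2 most abundant members of a list with fewer than 2 passing, and the 4 p38 genes. Where nothing passed, the 5 genes of smallest unadjusted p in each direction were taken. Genes named beside the rule were chosen after their values were seen: NFKBIA, MX1, ESM1, ADAMTS12, MYEOV, IGFBP3, MUC16 and SIRPA, and genes carried from 1 comparison to another. Against a group with 0 reads a fold is given as at least the value that 3 reads would yield. Log2 values against groups with 0 or few reads depend on the pseudocount. Exact 95% intervals of read ratios cover counting error only.

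Simulations with the mean levels and depths of these libraries (5 per comparison, 200 changed genes each) gave the share of planted changes called. Changes were planted in well-expressed genes only. Spread was drawn alike in all libraries and independently between genes, without a length trend or a wider knockout pair. The shares may therefore be too high for the real data. For the wild-type response 3.6% of 2-fold, 82.4% of 4-fold and 97.2% of 8-fold changes were recovered, with 13.2 false calls per simulation. For knockout against wild type under IL-1α the shares were 20.4%, 92.8% and 98.8%, with 11 false calls. For the interaction they were 0%, 23.2% and 73.2%, with 5.8 false calls. The knockout response has the layout of the wild-type response and was not simulated separately. Tables and figures were made with Python (3.11.15), numpy (2.4.6), pandas (2.3.3) and matplotlib (3.10.9).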

Results

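Transcript levels were measured in 6 HaCaT keratinocyte libraries, wild-type or p38α-knockout by their labels, without stimulation or after 4 h of IL-1α. Depth, recovered from the values, was 16726884 reads in the unstimulated wild-type library, 16295005 and 18535680 in the wild-type IL-1α libraries, 34967480 in the unstimulated knockout library and 21888588 and 29770283 in the knockout IL-1α libraries. Of these, 80.1% to 83.2% fell in exons. The 10 most abundant genes took 3.56% to 4.17% of exon reads. The wild-type IL-1α pair correlated at 0.985 across genes and the knockout IL-1α pair at 0.969, below the 0.982 between knockout replicate 1 and the unstimulated knockout library. Of 9272 genes reaching 5 RPKM, 6 lay at least 4-fold apart between the wild-type pair and 23 between the knockout pair. Among these were CCL2, a monocyte-attracting chemokine (206 and 8.87 RPKM), and DPYSL3, a cytoskeletal regulator (22.4 and 1.02 RPKM).

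MAPK14, which encodes the p38α kinase targeted in the knockout (chromosome 6, 35995454 to 36079013, hg19), was still transcribed in the edited cells. Its level was 14.4 RPKM in the unstimulated wild-type library, 13.3 and 14.8 RPKM in the wild-type IL-1α libraries, 11.3 RPKM in the unstimulated knockout library and 11 and 7.41 RPKM in the knockout IL-1α libraries. The log2 difference of knockout from wild type was -0.61 ± 0.22 (SE) under IL-1α (adjusted p = 0.301) and -0.34 without it. A value per whole gene does not reveal a frameshift or a small deletion, so the loss of p38α protein was neither shown nor excluded. The other p38 kinases read, in the same library order, MAPK11 (p38β) at 2.47, 2, 1.44, 2.71, 3.07 and 2.66 RPKM, MAPK12 (p38γ) at 7.64, 5.83, 5.45, 9.81, 8.64 and 6.15 RPKM, and MAPK13 (p38δ) at 8.02, 6.11, 6.50, 8.76, 7.98 and 5.14 RPKM.

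**Figure D1:**
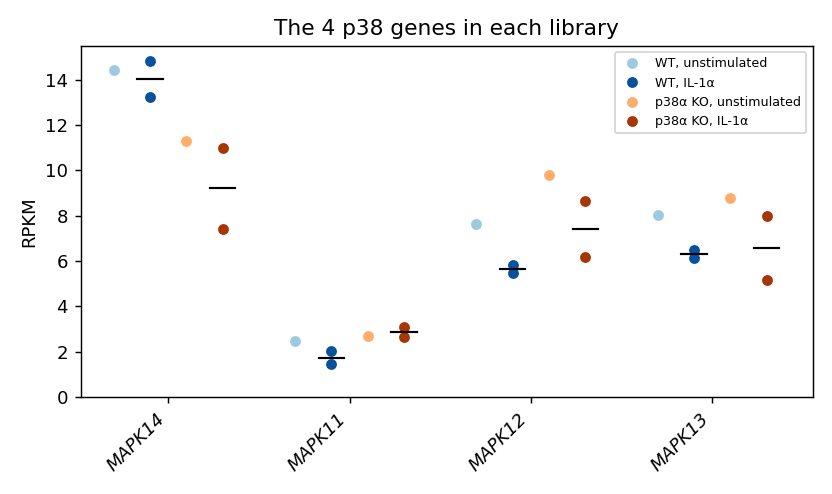
RPKM (vertical axis) of MAPK14, MAPK11, MAPK12 and MAPK13 in each library, grouped by genotype and stimulation; each point is 1 library and horizontal bars mark the mean of the 2 IL-1α libraries.

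In wild-type cells IL-1α raised small proline-rich proteins of the cornified envelope, chemokines that draw neutrophils and lymphocytes, and brakes on NF-κB signalling. SPRR2A, an envelope precursor (chromosome 1, 153028596 to 153029988), went from 4.80 to 389 ± 133 RPKM (SD, n = 2; log2 fold change 6.16 ± 0.31 SE, adjusted p = 0.00516), and SPRR2D rose by 6.87 (adjusted p = 0.00516). Its relatives SPRR2F (7.91, at least 452-fold, adjusted p = 0.00773) and SPRR2E (7.62, adjusted p = 0.0134) rose as well, though the 4 paralogs may share reads. CXCL8, the main neutrophil attractant of epithelia (chromosome 4, 74606223 to 74609433), rose from 17.7 to 249 ± 52.7 RPKM (3.76 ± 0.38, adjusted p = 0.0358). Other chemokines that rose were CCL5 (4.45, adjusted p = 0.0134), CXCL5 (4.08, at least 111-fold, adjusted p = 0.0478), CXCL6 (3.73, adjusted p = 0.0446) and CCL20, with 1 read before stimulation (ratio 97.0, 95% interval 17.2 to 3850; log2 3.69, adjusted p = 0.0281). The survival and ubiquitin-editing regulators BCL2A1 (5.45, at least 105-fold, adjusted p = 0.0134), BIRC3 (3.07, adjusted p = 0.00773) and TNFAIP3 (3.05, adjusted p = 0.0297) rose. So did the protease inhibitor PI3 (4.58, adjusted p = 0.0289), the growth-factor-like IGFL1 (3.77, adjusted p = 0.0134), the plasminogen activator PLAT (2.50, adjusted p = 0.0134) and the superoxide dismutase SOD2 (2.44, adjusted p = 0.0446). SLC39A2, a zinc importer (-2.01, adjusted p = 0.0478), and SNHG19, a short host RNA of small nucleolar RNAs (-1.77, adjusted p = 0.0446), fell. Both falls were fragile: 0 genes passed as lower with a pseudocount of 0.1, quantile normalization or voom weights. SNHG19 ran from -1.86 to -1.10 over the settings, and transcripts under 1 kb as a class had a median of -0.58 in wild type. In all, 28 of 12925 genes passed in limma, 26 up and 2 down, while 2333 genes had unadjusted p below 0.05 (606 up, 1727 down) against 646 expected by chance. The median of all genes lay at -0.14 and was brought to 0.00 by median-of-ratios rescaling, after which 53 genes passed. Voom weights left 11, and removing a trend with transcript length left 101. Leaving out 1 IL-1α library leaves a single replicated pair to measure the spread, so only sizes are given. Over all settings, those fits included, SPRR2A ran from 5.80 to 6.76, CXCL8 from 3.55 to 4.06 and CXCL5 from 3.16 to 9.37.

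**Figure D2:**
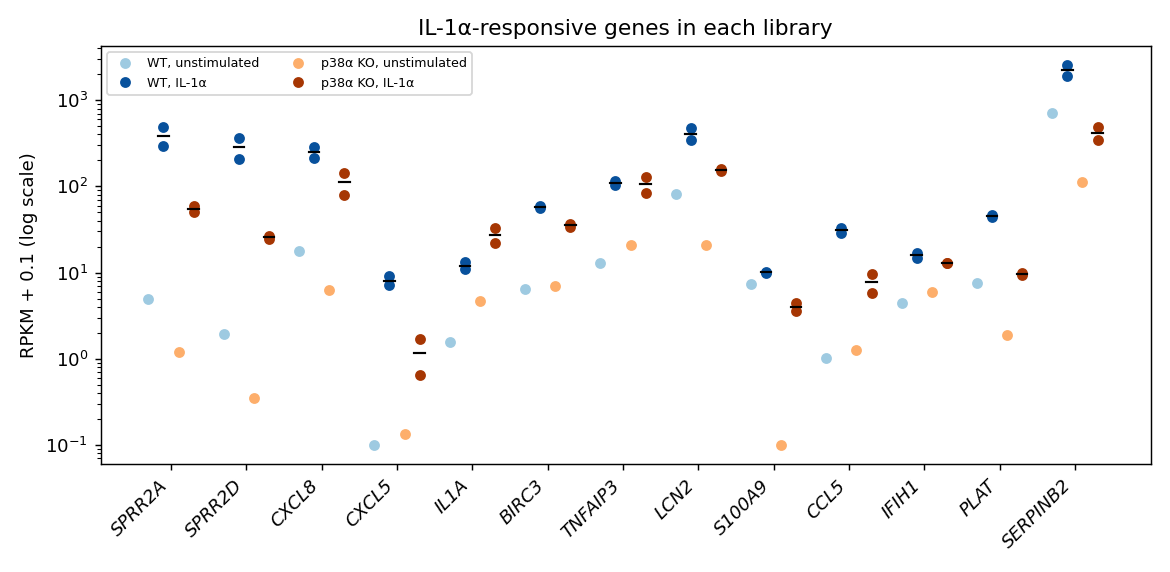
RPKM + 0.1 on a log axis (vertical) of genes tied to the IL-1α response in each of the 6 libraries; points are single libraries, coloured by genotype and stimulation, and bars mark the mean of the 2 IL-1α libraries.

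The gene lists placed these genes among broad inflammatory programmes in wild-type cells. All 6 measured CXC chemokines of the neutrophil-attracting list had positive changes (median 3.67, 3 passing, 6 adjusted over the list alone; camera adjusted p = 2.6e-11, adjusted p = 0.189 with an estimated correlation). Of 17 cytokines and colony-stimulating factors, which carry the alarm to neighbouring cells, IL1A (2.67, adjusted p = 0.0446), CSF2 (2.66, adjusted p = 0.026) and IL32 (2.69, adjusted p = 0.0491) rose and 10 passed within the list, IL1B with them at 2.33 (camera adjusted p = 3.7e-12, adjusted p = 0.189 with an estimated correlation). Of 8 other chemokines, 2 passed and 6 within the list (median 1.65, camera adjusted p = 6.94e-10, adjusted p = 0.189 with an estimated correlation). The 27 NF-κB subunits and feedback regulators were all higher (median 0.88, 3 passing, 16 within the list, NFKBIA among them at 1.82; camera adjusted p = 7.49e-21, adjusted p = 0.189 with an estimated correlation). Interferon-stimulated genes, which restrict viruses, were higher in 34 of 37 (median 0.90): the RNA sensor IFIH1 passed (1.75, adjusted p = 0.0478) and 16 passed within the list, such as MX1 (3.02; camera adjusted p = 2.36e-20, adjusted p = 0.189 with an estimated correlation). Matrix proteases and the plasminogen system were higher in 15 of 22 (median 1.06, 1 passing, 9 within the list; camera adjusted p = 1.86e-08, adjusted p = 0.291 with an estimated correlation), with MMP13, a collagenase, at 2.56. Antimicrobial genes (13, median 0.59) had 2 passing, LCN2, an iron-sequestering lipocalin, at 2.29 (adjusted p = 0.0446), and PI3 (camera adjusted p = 0.00382, adjusted p = 0.427 with an estimated correlation). All 14 replication-dependent histones were lower (median -1.05, 0 passing, 8 within the list; camera adjusted p = 1.47e-05, adjusted p = 0.189 with an estimated correlation), HIST1H1C at -1.11. The histone median was -0.49 with the length trend removed. Of 30 keratinocyte differentiation genes the 4 SPRR2 genes rose while the median was -0.44 against a mean of 0.89, and the list did not pass (camera adjusted p = 0.147). In all 18 lists passed with the preset correlation, 16 up and 2 down, and 0 with an estimated one. Up here is relative to all genes, whose median lay at -0.14: p38 pathway components, called up, had a median of 0.02.

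In knockout cells IL-1α again raised small proline-rich proteins, CXCL8 and antimicrobial genes. SPRR2A (log2 fold change 5.10, adjusted p = 0.025) and SPRR2D (5.12, adjusted p = 0.025) rose, as did CXCL8, from 6.19 to 112 ± 45.3 RPKM (4.00, adjusted p = 0.0469). S100A9, a calcium-binding subunit of calprotectin, had 0 reads in the unstimulated knockout library and rose at least 26.4-fold (3.13, adjusted p = 0.03), and LCN2 rose by 2.89 (adjusted p = 0.0387). SERPINA3, an acute-phase protease inhibitor with 2 reads before stimulation, rose (ratio 221, 95% interval 60.8 to 1830; log2 4.00, adjusted p = 0.025). IGFL1 (3.27, adjusted p = 0.0387), BIRC3 (2.26, adjusted p = 0.0387) and PLAT (2.12, adjusted p = 0.0427) complete the 9 genes that passed in limma, all up, with 463 genes at unadjusted p below 0.05, fewer than the 646 expected by chance. PI3 (3.99, adjusted p = 0.0652), CCL20 (3.24, adjusted p = 0.0652), CSF2 (2.23, adjusted p = 0.0652), IL1A (2.41, adjusted p = 0.0928) and TNFAIP3 (2.30, adjusted p = 0.0928) did not pass here. With the length trend removed 32 genes passed, 21 up and 11 down. Over all settings, those without 1 IL-1α library included, SPRR2A ran from 4.72 to 5.59, CXCL8 from 3.58 to 4.43 and S100A9 from 2.29 to 7.30.

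By list, the NF-κB and CXC chemokine programmes also passed in the knockout. All 27 NF-κB genes were higher (median 0.89, BIRC3 passing, 15 within the list; camera adjusted p = 3.05e-30, adjusted p = 0.17 with an estimated correlation). The 6 CXC chemokines had a median of 2.49 (1 passing, 6 within the list; camera adjusted p = 1.1e-14, adjusted p = 0.223 with an estimated correlation) and the 8 other chemokines 1.59 (0 passing, 6 within the list; camera adjusted p = 5.79e-14, adjusted p = 0.222 with an estimated correlation). Cytokines and colony-stimulating factors (median 0.99, 0 passing, 8 within the list) gave camera adjusted p = 4e-18, and adjusted p = 0.17 with an estimated correlation. The antimicrobial list stood at a median of 1 (2 passing, 5 within the list; camera adjusted p = 9.44e-09, adjusted p = 0.355 with an estimated correlation). Interferon-stimulated genes were higher in 31 of 37 (median 0.65, 0 passing, 3 within the list; camera adjusted p = 2.1e-14, adjusted p = 0.223 with an estimated correlation), with MX1 at 1.16. Histones, at a median of -0.08, did not pass (camera adjusted p = 0.388). In all 14 lists passed, all up, and 0 with an estimated correlation.

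**Figure D3:**
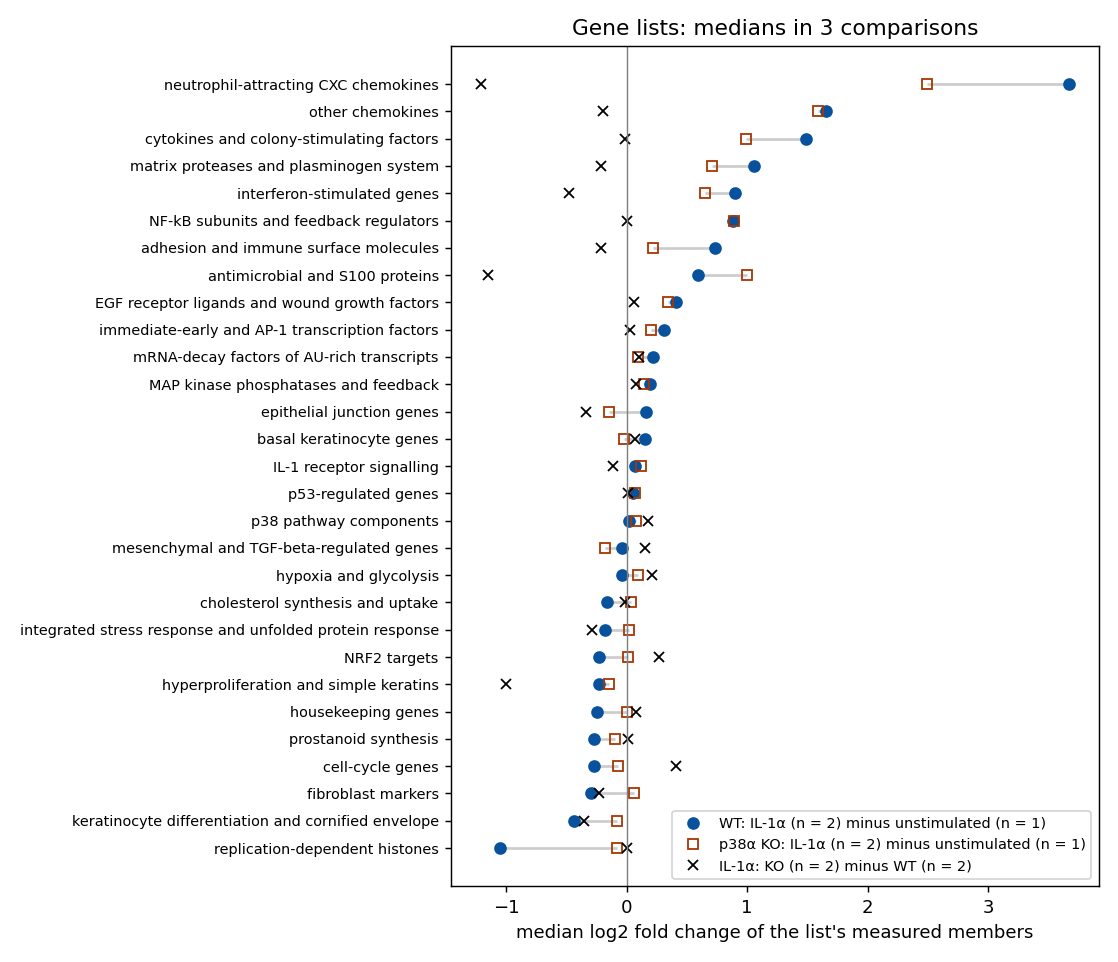
Median log2 fold change (horizontal axis) of the members of each gene list (vertical axis) for the IL-1α response in wild type and in knockout and for knockout against wild type under IL-1α; each mark is 1 list median, and lists with few measured members are left out.

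Under IL-1α, knockout cells had lower levels of SPRR2 envelope genes, of PLAT and SERPINB2 of the plasminogen system and of MMP13 than wild-type cells, and higher levels of BASP1, CALB2 and TXNIP. SERPINB2, the plasminogen activator inhibitor of keratinocytes (chromosome 18, 61554939 to 61571124), stood at 2239 ± 456 RPKM (SD, n = 2) in wild type and 420 ± 101 RPKM in knockout (-2.42, adjusted p = 0.0492), and the activator PLAT was lower too (-2.18, adjusted p = 0.028). The osteoprotegerin gene TNFRSF11B (-2.90, adjusted p = 0.028), the collagenase MMP13 (-3.06, adjusted p = 0.0492) and the cytidine deaminase APOBEC3A (-4.14, adjusted p = 0.0492) were lower. So were SPRR2D (-3.40, adjusted p = 0.0342), SPRR2A (-2.78, adjusted p = 0.0421), IGFL1 (-2.30, adjusted p = 0.0467), the hair keratin-associated KRTAP3-1 (-3.08, adjusted p = 0.0465), the calcium-binding S100P (-2.38, adjusted p = 0.0421) and the GABA receptor subunit GABRP (-2.28, adjusted p = 0.0421). Among genes chosen after their values were seen, the growth-factor-binding IGFBP3 (-2.21, adjusted p = 0.0342), MYEOV (-1.95, adjusted p = 0.043) and the mucin MUC16 (-1.77, adjusted p = 0.0492) were lower. The proteoglycan ESM1 (2.63, adjusted p = 0.0483) and the metalloprotease ADAMTS12 (2.29, adjusted p = 0.0483), chosen likewise, were higher. BASP1, a membrane-bound cytoskeletal regulator (chromosome 5, 17216932 to 17276954), stood at 7.94 ± 0.556 RPKM in wild type and 41.4 ± 1.99 RPKM in knockout (2.31 ± 0.16 SE, adjusted p = 0.028). Higher with it were the calcium buffer CALB2 (2.18, adjusted p = 0.0342), the microtubule regulator STMN3 (1.53, adjusted p = 0.0467) and TXNIP, a thioredoxin inhibitor (6.39 against 30.3 RPKM, 2.16, adjusted p = 0.0345). In limma 20 of 12925 genes passed, 6 up and 14 down, with 1926 at unadjusted p below 0.05 against 646 expected by chance. The count was 0 without the variance trend and 55 with voom weights. Over all settings, those without 1 IL-1α library included, BASP1 ran from 2.20 to 2.38 and APOBEC3A from -7.47 to -3.40.

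**Figure D4:**
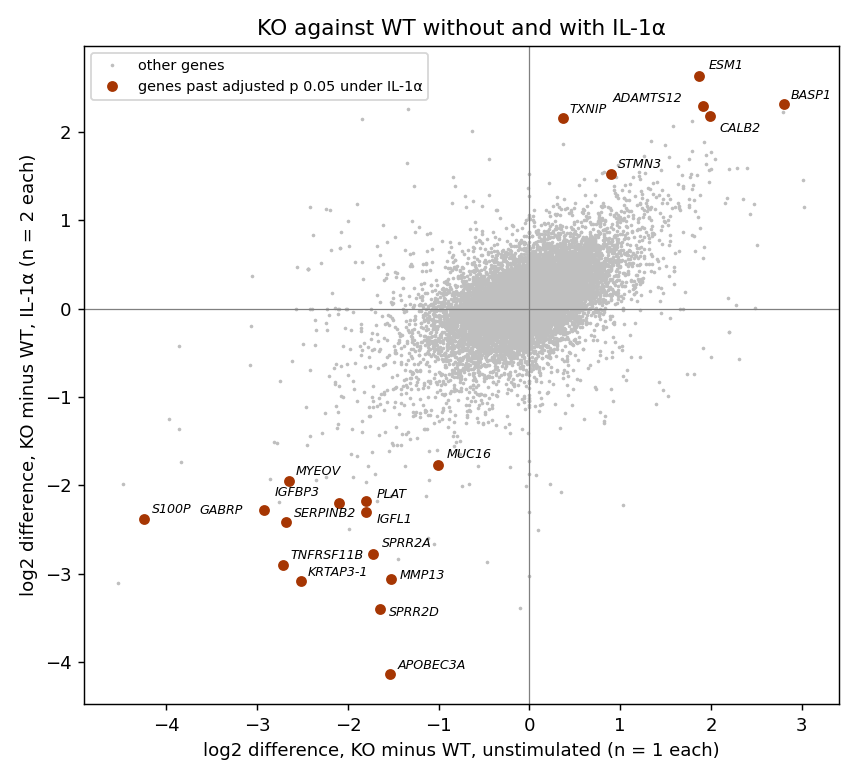
Log2 difference of knockout from wild type without stimulation (horizontal axis, 1 library per genotype) and under IL-1α (vertical axis, 2 libraries per genotype); each point is 1 gene, and genes passing under IL-1α at adjusted p below 0.05 are coloured.

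Several inflammatory and keratinocyte lists were lower in knockout than in wild type under IL-1α, and the cell-cycle list was higher. All 13 antimicrobial genes were lower (median -1.15, 0 passing, 6 within the list; camera adjusted p = 4.42e-10, adjusted p = 0.423 with an estimated correlation), LCN2 at -1.37 and S100A9 at -1.25. All 6 CXC chemokines were lower (median -1.21, 0 passing, 5 within the list; camera adjusted p = 2.86e-06, adjusted p = 0.423 with an estimated correlation), CXCL8 at -1.20 and CXCL1 at -1.21. Over the settings CXCL8 ran from -1.62 to -0.77 and CXCL1 from -1.81 to -0.61. Of 37 interferon-stimulated genes 31 were lower (median -0.48, 0 passing over all genes, 11 lower and 1 higher within the list; camera adjusted p = 4e-09, adjusted p = 0.423 with an estimated correlation), MX1 at -1.25. Keratinocyte differentiation genes were lower in 24 of 30 (median -0.35, 2 passing, 14 lower and 2 higher within the list; camera adjusted p = 8.5e-10, adjusted p = 0.423 with an estimated correlation). Hyperproliferation-associated and simple keratins, which include the scaffold of wounded epidermis, were lower in 8 of 9 (median -1, 0 passing, 3 within the list; camera adjusted p = 2.49e-05, adjusted p = 0.423 with an estimated correlation), KRT17 at -2.12. Matrix proteases and the plasminogen system had 3 passing genes, all lower, with 9 lower and 3 higher within the list (median -0.21, camera adjusted p = 0.000626, adjusted p = 0.541 with an estimated correlation). Cell-cycle genes were higher in 43 of 44 (median 0.41, 0 passing, 11 within the list; camera adjusted p = 4.41e-09, adjusted p = 0.423 with an estimated correlation). The NF-κB list lay at 0.00, with 13 genes higher and 14 lower (camera adjusted p = 0.435). In all 10 lists passed, 1 up and 9 down, and 0 with an estimated correlation. CCL2 lay at -2.08 (adjusted p = 0.482), and at 0.15 without knockout replicate 2.

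Whether the response itself differed between genotypes was asked by the interaction. S100A9 had the smallest p: it went from 0 to 3.90 ± 0.547 RPKM in knockout and from 7.32 to 9.95 ± 0.338 RPKM in wild type (log2 interaction 2.71, adjusted p = 0.75). With 0 reads at the start in knockout that size is set by the pseudocount, and it ran from 1.89 to 6.86 over the settings tried. The chemokine CCL5 reached 30.7 ± 3.26 RPKM in wild type and 7.60 ± 2.76 RPKM in knockout (-2.21, adjusted p = 0.966), and CXCL5, with 0 reads at the start in wild type, lay at -2.60 (adjusted p = 0.966; from -4.88 to -2.10 over the settings). Adjusted over their own list alone S100A9, CCL5 and CXCL5 passed. CXCL8 changed by 3.76 in wild type and 4.00 in knockout (interaction 0.24, adjusted p = 0.978), turning to -0.18 without knockout replicate 2 and to -0.04 with the length trend removed. RPL39, a ribosomal protein gene, stood at 152, 50.4 and 41.1 RPKM in wild type and at 29.5, 38.7 and 37.7 RPKM in knockout (2.10, adjusted p = 0.786), and SNHG19 lay at 1.83 (adjusted p = 0.806). Over the settings RPL39 ran from 1.39 to 2.24 and SNHG19 from 1.12 to 1.91. In limma 0 genes passed over all genes, 567 had unadjusted p below 0.05 against 646 expected by chance, and voom gave 0 as well. The simulations, with equal spread in all groups and no length trend, recovered 23.2% of 4-fold and 73.2% of 8-fold interactions. Smaller ones would mostly be missed.

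By list, interferon-stimulated genes responded less in knockout, histones differed the other way, and CXC chemokines were split. Interferon-stimulated genes had a median interaction of -0.46, 32 of 37 lower (camera adjusted p = 3.23e-09, adjusted p = 0.546 with an estimated correlation), with MX1 at -1.85. CXC chemokines lay at a median of -0.53, with 4 of 6 lower and 2 higher (camera adjusted p = 0.0201, adjusted p = 0.546 with an estimated correlation) and histones at 0.82, all 14 higher (camera adjusted p = 6.62e-05, adjusted p = 0.546 with an estimated correlation), HIST1H1C at 1.41. With the length trend removed the histone median was 0.36 (camera adjusted p = 0.0456) and that of CXC chemokines -0.95. Of 288 genes at least 2-fold higher under IL-1α in wild type, 212 (73.6%, 95% interval 68.1 to 78.6) were lower in knockout than in wild type under IL-1α, against 39% of all genes. Choice and comparison here use the same wild-type libraries, and the interval treats genes as independent and leaves out the spread between libraries. Chosen on wild-type replicate 1 and compared on replicate 2, the share was 71.9% (39.5% of all genes), and the other way round it was 51.8% (40.5% of all genes). Chosen on the knockout response instead, it was 51.3%, a choice that favours high knockout values. With a log2 induction of at least 2 the share was 89.1% for genes chosen on both wild-type replicates. It was 82.9% when chosen on replicate 1, 71.6% on replicate 2 and 69.8% on the knockout, each above the share of all genes.

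Without stimulation, knockout cells already had less of many keratinocyte defence and differentiation genes, by fold change in 1 library per genotype and with no test. The matrix-degrading MMP7 stood at 13.4 RPKM in wild type and 0.102 RPKM in knockout (log2 -4.53), S100P at 105 and 5.09 RPKM (-4.24), and S100A9 was at least 48.8-fold lower (-3.97). The envelope precursor IVL (-1.80), the suprabasal keratins KRT13 (-1.98) and KRT16 (-1.90), the desquamation protease KLK7 (-2.11), SERPINB2 (-2.68), GABRP (-2.92), LCN2 (-1.96) and PLAT (-1.80) were lower. The IL-1 receptors IL1R1 (-1.51) and IL1R2 (-1.36) were also lower, with CXCL8 at -1.44 and CXCL6 at -1.45, while IL1A (1.39) and IL1B (1.24) were higher. Higher too were BASP1 (2.80), the zinc finger gene ZNF618 (2.79), DPYSL3 (2.50), CALB2 (1.99), the p38 activator MAP2K6 (1.97) and the proliferation marker MKI67 (1.22). DPYSL3 read only 1.02 RPKM in knockout IL-1α replicate 2, below every wild-type library. In all 844 of 12608 genes differed at least 2-fold, 313 higher and 531 lower. With the length trend removed 642 did, 410 higher and 232 lower, and only 459 of the 844 were among them. Of the 844, 313 differed at least 2-fold the same way in knockout IL-1α replicate 1 against the wild-type IL-1α mean, and 176 in replicate 2.

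Antimicrobial genes (median -1.41, percentile 0 among random lists), histones (-0.83, percentile 0), keratinocyte differentiation genes (-0.43, percentile 0.01) and integrated stress response genes (-0.41, percentile 0.17), CHAC1 at -2.25 among them, lay low in the unstimulated knockout. With the length trend removed these medians were -0.84, -0.32, -0.38 and -0.24, so part of these differences went with that trend. Prostanoid synthesis genes (-0.54, percentile 0.61) and CXC chemokines (-0.68, percentile 0.83) lay low as well. With the length trend removed they stood at -0.57 and -0.31. The median of hyperproliferation-associated and simple keratins (-0.45) lay at percentile 16.1, and was -0.24 with the length trend removed. Members of that list nonetheless passed the 2-fold rule: KRT4, KRT13, KRT16 and KRT17. Cell-cycle genes lay high (0.28, percentile 100). So did hypoxia and glycolysis genes (0.15, percentile 99.5), basal keratinocyte genes (0.12, percentile 99.1), p38 pathway components (0.22, percentile 98.7) and mesenchymal genes (0.19, percentile 98.6). With the length trend removed the medians of these 5 lists were 0.35, 0.14, -0.05, 0.22 and 0.18, in the same order. A percentile ranks a list within 1 pair of libraries, so it cannot separate genotype from other differences between those 2 libraries. The NF-κB list (0.11, percentile 92.6) and interferon-stimulated genes (0.06, percentile 79.8) did not stand apart. Markers of other skin cell types were scarce: 4 fibroblast, 1 melanocyte, 2 leukocyte and 1 endothelial marker were measured, and none of these lists passed in any tested comparison. Single members did move. Adjusted within their lists, S100A4, CD68 and CDH5 passed for the wild-type response, and LUM, COL6A1, LCP1 and CD68 between genotypes under IL-1α. Over lists this short the adjustment is slight, and for CDH5, the 1 measured gene of its list, there is none. CDH5 read 1.45 RPKM without and 11.4 and 11.8 RPKM with IL-1α in wild type.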

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

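The tests in this part were chosen after the data were seen, and so were the 4 genes at the end of it. Each SE of a median here was taken over the genes of the set as if they were independent. It does not measure the spread between cultures. For a different response between genotypes 0 genes passed over all genes, and S100A9, CCL5 and CXCL5 passed over their own list alone. The lists that passed camera for it all lost the call with an estimated correlation.

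The wild-type libraries differed by transcript length, the unstimulated one most. The Spearman correlation of a library's deviation with length was -0.58 in the unstimulated wild-type library, -0.29 and 0.46 in the wild-type IL-1α pair, and 0.18, 0.26 and 0.25 in the knockout libraries. The difference between the 2 wild-type IL-1α libraries, treated alike, correlated with length at -0.68, and that of the knockout pair at -0.05. The trend therefore also runs through the wild-type pair that helps to set the residual spread. Transcripts under 1 kb had a median wild-type response of -0.58, those over 3 kb 0.07. The 80 ribosomal protein genes had a median of -0.57 in wild type and 0.02 in knockout. With the length trend, fitted without them, removed, their wild-type median was -0.04, so a length trend between libraries, such as from RNA integrity or size selection, may be the whole of their fall. An IL-1α response as the whole of it cannot be told apart from this: the 2 wild-type IL-1α libraries, treated alike, differed by 0.31. RNA integrity values and further wild-type libraries with and without IL-1α would help to tell.

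Histones share part of this pattern. Their wild-type median of -1.05 became -0.48 (SE 0.12) with the length trend removed, so that removal did not account for the whole fall. Their median interaction of 0.82 and their unstimulated difference of -0.83 rest on the same unstimulated wild-type library. With the length trend removed they became 0.36 (camera adjusted p = 0.0456) and -0.32. Histone messages mostly lack poly-A tails, and in a poly-A library their level may also follow tail-selection efficiency or the share of cells in S phase; neither was tested.

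Between genotypes under IL-1α the length trend was small, with median differences of -0.03 for transcripts under 1 kb, 0.05 for 1 to 3 kb and 0.12 over 3 kb. With it removed 19 of the 20 genes that passed still did, a weak check since there was little to remove. As a group, the 20 genes do not look like a difference that only IL-1α brings out. In the unstimulated libraries, which do not enter the difference under IL-1α, all 20 differed in the same direction, with a median of 1.89 (SE 0.19) against 2.31 under IL-1α. They may come from the same clones or cultures as the IL-1α libraries, so this is no independent repeat. Sizes differed in places: TXNIP (2.16 with against 0.37 without IL-1α) and MMP13 (-3.06 against -1.53) differed more under IL-1α and S100P less (-2.38 against -4.24), but 0 genes passed the interaction test over all genes. For APOBEC3A (3 against 27 reads without IL-1α) and SPRR2D (6 against 21 reads) the unstimulated log2 values are drawn towards 0 by the pseudocount and are not compared in size. Across genes the 2 differences correlated at 0.53. A standing difference between the cell populations is consistent with this, and loss of p38α or divergence of clones would look the same; cells re-expressing p38α, or a p38 inhibitor in wild-type cells, would tell.

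The standing difference was not carried evenly by the knockout pair. The 844 genes past the fold rule without IL-1α had a median difference, signed as without IL-1α, of 0.72 in knockout replicate 1 and 0.35 in replicate 2 (SE 0.03 each). With the length trend removed 459 of the 844 stayed past the rule, and these medians were not repeated for them. For the set as a whole, a part that belongs to only 1 knockout culture cannot be told apart from a smaller shared difference. Of the 23 genes at least 4-fold apart in the knockout pair, the unstimulated knockout library lay nearer replicate 1 in 20. SIRPA read 9.06 RPKM unstimulated, 8.46 in replicate 1 and 0.845 in replicate 2, and DPYSL3 read 25.2, 22.4 and 1.02. In the wild-type libraries SIRPA read 2.03, 1.89 and 1.78 RPKM and DPYSL3 4.04, 2.55 and 3.75. For these genes, picked for their distance in the pair, replicate 2 did not share the unstimulated difference. The replicates could be different clones, with the value of 0.35 in replicate 2 as what both share, and clone records or variants in the reads would tell.

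Interferon-stimulated genes responded less in the knockout (median interaction -0.46). A lower start was not seen in the 1 unstimulated library of each genotype, where their median difference was 0.06 (SE 0.09). Removing the length trend did not account for the weaker response either, with the interaction at -0.53 (SE 0.08). CXC chemokines (-0.53, 4 of 6 lower) are less clear: their unstimulated median of -0.68 (SE 0.28) leaves a lower start and a weaker response hard to separate, so these cannot be told apart. A weaker stimulus of the knockout cultures cannot be told apart for either list. The NF-κB list, at 0.88 in wild type and 0.89 in knockout as deposited, had a knockout to wild-type ratio of 0.75 with the length trend removed. A dose or time series of IL-1α in both genotypes would separate these.

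The other lists that passed camera for the interaction were NF-κB regulators (-0.10), matrix proteases and the plasminogen system (-0.24), keratinocyte differentiation (-0.16, a call that ended under median-of-ratios rescaling, adjusted p = 0.0692) and epithelial junction genes (-0.42). Camera sets a list against all other genes, whose median interaction lay at 0.10, so these calls do not place a median away from 0. The NF-κB list had near-equal median responses as deposited, 0.88 in wild type and 0.89 in knockout. Its median interaction was -0.23 with the length trend removed. Among genes picked from the naming rule or beside it, 4 had all replicates of 1 genotype above its unstimulated library and all of the other below. None passed the interaction test over all genes, and both replicates of a genotype share 1 unstimulated library. Wild-type minus knockout response was -0.63 for STMN3, 0.57 for KRTAP3-1, -2.10 for RPL39 and 1.36 for RIMKLB. The replicates read, wild type first, -0.44 and -0.57 against 0.10 and 0.17 for STMN3, 0.91 and 0.18 against -0.02 and -0.03 for KRTAP3-1, -1.58 and -1.88 against 0.39 and 0.35 for RPL39, and 0.35 and 0.49 against -0.11 and -1.78 for RIMKLB. The knockout values of KRTAP3-1 rest on 7 reads with IL-1α and 5 without (ratio 0.948, 95% interval 0.259 to 3.79) and show no movement. Ribosomal protein genes as a group shared the lower wild-type values of RPL39 but not the higher knockout ones (median 0.02).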

How the results depend on the processing

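The length-trend removal, the fit without the wild-type unstimulated library, and the choice of induced genes on the knockout response were added after the data were seen; the rest was set before. Each symbol has 1 line in the table, so a repeat on duplicate lines did not apply. The wild-type response count (28, 26 up) was 264 without the low-value filter (7 up, 257 down, 3 of the 28 kept), 107 with a mean of at least 1 RPKM, 53 after median-of-ratios rescaling, 11 with voom weights, 101 with the length trend removed (95 up, 6 down) and 37 without the variance trend (20 up, 17 down); leaving out 1 IL-1α library gave 0 to 46 calls, 0 without either wild-type replicate. The knockout response (9) gave 5 with a pseudocount of 1, 614 without filter (11 up, 603 down), 38 with the mean filter, 4 without the trend, 2 with voom and 32 with the length trend removed. Knockout against wild type under IL-1α (20, 6 up) gave 7 with a pseudocount of 0.1 and 2 without filter, where 0 of the 20 were kept. It gave 78 with the mean filter (31 up), 13 after quantile normalization and 0 without the trend. With voom it gave 55 (21 up) and with the length trend removed 43 (12 up). Without the wild-type unstimulated library this comparison gave 20, 19 of them the same. With replicate number as a replicate block it gave 62, all 20 kept, though deviations of equally numbered replicates correlated at only 0.009, so the numbers give no sign of pairing. The interaction (0) stayed at 0 except for 758 without filter. It, the wild-type response and the unstimulated comparison cannot be run without the wild-type unstimulated library. The unstimulated fold count (844, 313 up) was 469 with a higher value of at least 5 RPKM and 642 with the length trend removed (410 up, 459 of the 844 kept). List calls over the tested contrasts (18, 14, 10 and 7) fell to 0 in each with an estimated correlation. They were 17, 13, 10 and 6 after median-of-ratios rescaling, and 13, 13, 10 and 9 with the length trend removed. The induced share (73.6%, against 39% of all genes) was 71.9% and 51.8% when genes were chosen on wild-type replicate 1 or 2 and compared on the other, and 51.3% when chosen on the knockout. With the length trend removed it was 69.8%, against 48.6% of all genes. Of the named genes, CCL2 under IL-1α (-2.08) ran from -4.31 without knockout replicate 1 to 0.15 without replicate 2, and the CXCL8 interaction (0.24) from -0.18 to 0.67, and was -0.04 with the length trend removed. MAPK13 without stimulation (0.12) was -0.14 with the length trend removed. No other repeated gene value changed sign. The TXNIP wild-type response and the STMN3, KRTAP3-1 and RIMKLB interactions, among others, were not repeated.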

Other observations

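These observations were made after the data were seen. MAP2K6, an upstream kinase of p38, stood at 0.612, 0.43 and 0.524 RPKM in the wild-type libraries and at 3.87, 3.15 and 1.79 RPKM in the knockout ones, in the order unstimulated and the IL-1α replicates. The difference under IL-1α was 1.57 (adjusted p = 0.15 over all genes in limma; passing over the p38 list alone). The signalling receptor IL1R1 stood at 10.6, 12.1 and 11.5 RPKM in wild type and 3.38, 2.76 and 5.06 RPKM in knockout (-1.53 under IL-1α, adjusted p = 0.134), while its ligands IL1A (1.12, adjusted p = 0.178) and IL1B (0.92, adjusted p = 0.225) read higher there. PTGS2, a known target of p38 through mRNA stability, read lower in knockout both without stimulation (-1.59) and under IL-1α (-1.40, adjusted p = 0.073).

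CCL2 read 9.75 RPKM without and 186 ± 20.6 RPKM (SD, n = 2) with IL-1α in wild type, and 12.6 RPKM without and 206 RPKM with it in knockout replicate 1, but 8.87 RPKM in replicate 2, while CXCL8 in that replicate read 144 RPKM. ICAM1 read 7.30 RPKM in knockout replicate 1 and 35.2 RPKM in replicate 2.

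TXNIP read 24.2 RPKM without and 5.78 and 7 RPKM with IL-1α in wild type (-1.85, adjusted p = 0.0579 in limma) and 31.3, 27.2 and 33.3 RPKM in knockout. TXNIP follows glucose and medium supply as well as signalling, and nothing here separates the 2.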
